A study of Mus musculus with 8 samples.

How the data were processed

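The samples were mouse cells (ICR strain) sorted by flow cytometry, with 1 array per sample and 8 arrays in all. Per the labels, 10 ng of total RNA was amplified with the NuGEN Pico system, and the product was labelled with Cy3 by an Agilent enzymatic kit. The 8 arrays lay on 1 slide and shared 1 scan time, 4 of them in each of 2 slide parts, which are called slide rows here. Both Wt1-GFP arrays lay in the second slide row.

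Per the file headers, each intensity is a processed signal of Agilent Feature Extraction 10.7.3.1, a 1-colour signal after background subtraction and detrending within the array. Raw mean signal, local background and flags for spots well above background, saturated or out of line came with each spot. The deposited matrix holds log2 values. Their scale is not given in the sources used here and was worked out from the numbers: they followed log2 of the processed signal relative to the 75th percentile of the array at r = 0.9999, centred on each probe's median over the 8 arrays (largest absolute probe median 0.005). The scanner values were used, and the matrix served as an alternative.

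Each array held 62976 spots, of which 59305 were not controls, from 55681 probes. Spots that Feature Extraction called outliers were left out, repeated spots were averaged, and 18 probes without a remaining spot on some array were dropped, which left 55663. The 75th percentile signal ran from 242.9 to 316.7, and the median local background from 25 to 31. The number of arrays limits the precision. Probes were named by the RefSeq accession they carry (26755), else by their own symbol where RefSeq lists it (3817), else by their own name (25091). Probes well above background on at least 1 of 8 arrays were tested, and a gene with several probes was represented by the probe with the highest mean, which gave 29544 names. Of 108 listed or named genes with at least 2 probes, 21 had probes that differed in the sign of the reporter difference. Probes of other genes differed in its size, so folds and bounds hold for the probe used. The brightest probes of Eya1, Nanog, Trp63, Csf1r, Elavl4, Prdm1 and Myod1 were nearly flat over the arrays, so these genes are not read as unchanged.

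Values were log2 processed signals minus the log2 of the array's 75th percentile. They were fitted with limma 3.58.1 in R 4.3.3, after reading with version 1.17.8 of data.table. The model had 5 group terms and a position term (0.5 for rostral, -0.5 for caudal, 0 for undivided samples), which left 2 residual degrees of freedom. Stages with 1 array were assumed to vary like the other groups. The comparisons were Hoxb7-GFP against Wt1-GFP at E9.5, the 3 steps between neighbouring stages, a line over embryonic day (8.75, 9.5, 10.5 and 11.5), rostral against caudal, and the interaction of position with reporter. A gene passed at Benjamini-Hochberg adjusted p 0.05. A fold is 2 to the power of the fitted difference. Where a gene was not well above background on every array of the dimmer group, the fold is a lower bound, written as at least N-fold. It is the brighter group's mean minus the dimmer group's, taking for each array not well above background the larger of the dimmest well-above level of that array (-5.03 to -3.95 on the log2 scale) and the gene's own level. Slopes are given only for genes measured on all 6 duct arrays.

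Gene lists numbered 31, with 412 names over all lists, of which 396 were measured. They covered duct transcription factors, bud tip, duct trunk, nephrogenic, coelomic, lateral plate, stromal and epithelial genes, anterior, middle and posterior Hox genes, the retinoic acid, FGF, Wnt, BMP, Notch and Hedgehog pathways, cell cycle, glycolysis, the early embryonic programme, primitive streak, somite, endothelium, blood, neural, neural crest, endoderm, surface ectoderm, heart and germ cell markers, and immediate early genes. Lists were tested with camera at its preset correlation of 0.01, with a correlation estimated from the residuals, and with fry, and adjusted over the 31 lists of a comparison. At the preset, camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes the residual degrees of freedom of the fit. The same lists also served as markers of other cell types.

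The lists, the rule for named genes, the comparisons and the first set of alternatives were written before the data were examined. The rule took 7 label and duct genes in each comparison, then up to 10 genes each way past the threshold (5 for stages with 1 array), filled to 5 by unadjusted p where fewer passed, and up to 4 members per list that passed or the 2 brightest. After the values were seen, genes with the largest differences past the threshold of the intensity trend, members past the threshold adjusted over the list alone, and markers of other cell types were added.

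The fits were tested on simulated data with the fitted levels of the real arrays, with 50 genes changed at each fold over 29544 genes. Spreads were drawn from the prior of the intensity trend fit, and genes varied independently. Better recovery with the trend is therefore partly built in and does not speak for the trend's calls on the real arrays. For Hoxb7-GFP against Wt1-GFP the plain fit recovered 0%, 0%, 0% and 34% of genes at 2-, 4-, 16- and 64-fold, with 1 unchanged gene called, and with the intensity trend 6%, 12%, 54% and 76%, with 3 unchanged genes called. For rostral against caudal the plain fit recovered 0%, 0%, 46% and 72%, and with the trend 8%, 28%, 66% and 86%, with 3 unchanged genes called in each. Camera found the 1 shifted list and called 0 others, while the estimated correlation missed it (adjusted p = 0.21). Because simulated genes varied independently, the 0 other calls say nothing about real lists whose genes vary together. Estimated correlations there reached 0.58 for cell cycle and 0.61 for heart genes. The miss shows that an estimated correlation can lose a shifted list whose genes are not correlated.

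The first set of alternatives comprised quantile normalization, normexp background correction with an offset of 50, no filter, filters at 2 or 8 arrays, the deposited matrix, an intensity trend in the prior variance, the mean over probes, no position term, other sets of arrays, and leaving out each array. After the data were seen, the slide row as a block, values floored at -3.95, the trend combined with other settings, and list tests on these settings and on the interaction were added. Only the E10.5 group had an array in each slide row, so the block was estimated from its rostral and caudal pair. It therefore cannot separate a row effect from a position difference particular to E10.5. The quality reports and images of the scanner were not analysed here, and no genome positions were used.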

Results

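The nephric (Wolffian) duct is an epithelial tube that extends from rostral to caudal through the intermediate mesoderm and later sends out the ureteric bud, the source of the kidney's collecting ducts. Duct precursors were sorted from mouse embryos by a Hoxb7-GFP reporter, and from E9.5 on the labels also state that the cells lacked Flk1 (Kdr), a receptor of endothelial cells. Intermediate mesoderm cells of E9.5 were sorted by a Wt1-GFP reporter. The 8 arrays formed 5 groups: duct precursors at E8.75 (1 array), E9.5 (2 arrays, a rostral and a caudal part), E10.5 (2 arrays, again rostral and caudal) and E11.5 (1 array of the bud), and Wt1-GFP cells at E9.5 (2 arrays, rostral and caudal). Between 60.6% and 69.2% of probes were well above background on an array, 0 probes were saturated, and arrays correlated at r = 0.912 to 0.963. Levels below are log2 signals relative to the 75th percentile of the array. The labels do not say that the arrays came from separate animals, and no group held repeats of the same kind of sample. For single genes the p-values therefore measure only how the rostral and caudal difference varied between the groups that were split. That spread may be technical or a real difference between stages and reporters, and it is no estimate of variation between animals. List p-values at the preset correlation set the members against all other genes and rest on the spread over genes. They do not carry the limit of 2 residual degrees of freedom, and their small size is no measure of repeatability between arrays or animals.

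Wt1 and Hoxb7 followed the labels of the sorts. Wt1, a transcription factor of nephrogenic and coelomic mesoderm, had levels of 4.08 and 4.01 in the Wt1-GFP cells and -0.2 and -1.94 in the E9.5 duct (log2 difference -5.12, SE 1.09, adjusted p = 0.29). It was not well above background on the E8.75 and the caudal E10.5 arrays. Hoxb7, the source of the reporter's promoter, was at 2.44 and 2.3 in the E9.5 duct, against 1.5 and 1.63 in Wt1-GFP cells. Kdr was at 4.12 at E8.75, where the labels state no selection against it, and between 1.47 and 1.95 on the later duct arrays. In Wt1-GFP cells, whose labels state no such selection either, it was at 2.1 and 2.1. The other, dimmer probe of Kdr ranged over 6.08 on the log2 scale across the arrays, against 2.65 for the probe used here. Pax2, Lhx1 and Gata3, transcription factors that specify the duct, were higher in the E9.5 duct by 3.26, 3.18 and 2.81 (SE 0.46, 0.36 and 0.4, adjusted p = 0.22, 0.2 and 0.22). Ret, the receptor through which GDNF drives bud outgrowth, was higher by at least 29.3-fold, adjusted p = 0.17, and was well above background on neither Wt1-GFP array.

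**Figure D1:**
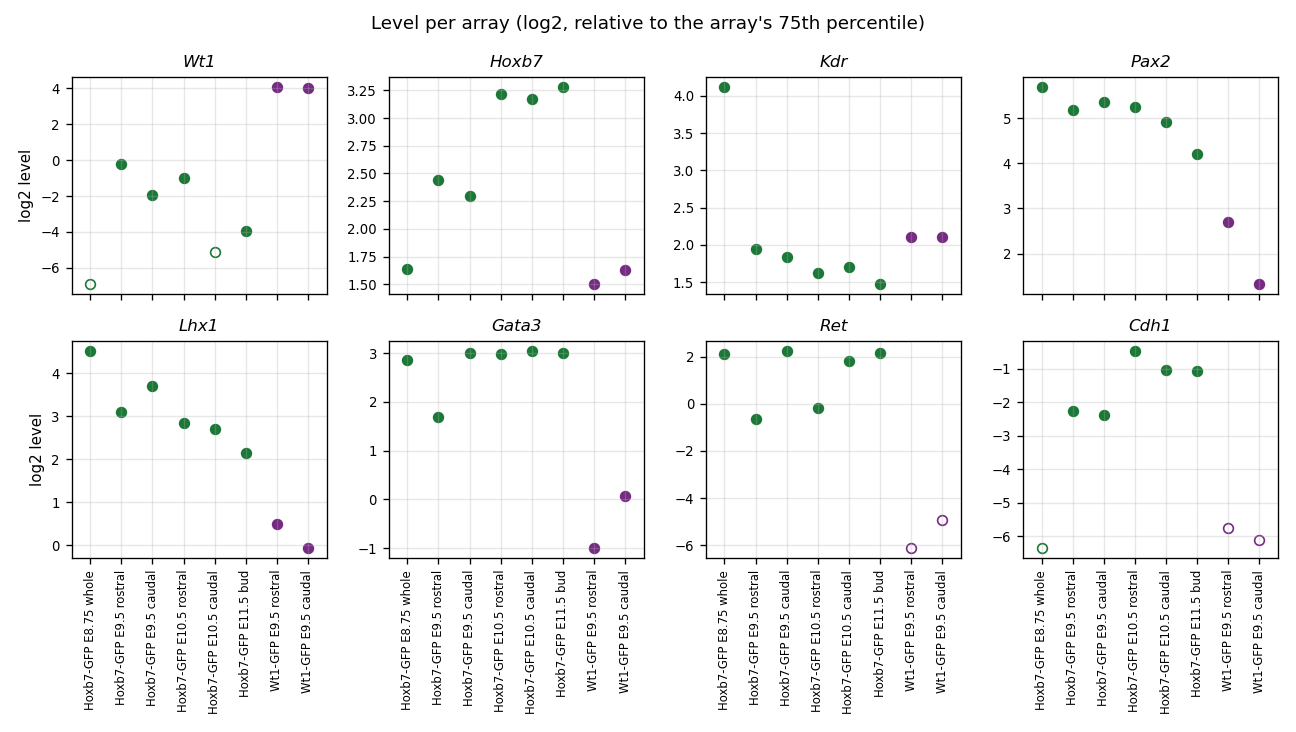
Level of 8 genes on each of the 8 arrays, as log2 signal relative to the 75th percentile of the array. Each point is 1 array, green for Hoxb7-GFP and purple for Wt1-GFP, filled where the gene was well above background and open where it was not.

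Duct precursors and intermediate mesoderm of the same day differed along an epithelial and mesenchymal axis. Lists of epithelial and duct genes were higher in Hoxb7-GFP cells, and those of stroma, coelomic epithelium and lateral plate were higher in Wt1-GFP cells. No single gene passed adjusted p 0.05 in limma's plain fit (0 of 29544, lowest adjusted p = 0.17), while 3935 genes had unadjusted p under 0.05, 1906 higher and 2029 lower, where 1477 would arise by chance. With a prior variance that followed intensity, 632 genes passed, 292 higher and 340 lower in the duct. That count was 362 without the rostral E9.5 duct array, 1 without the caudal one, 0 without either E10.5 array, 174 without the caudal Wt1-GFP array, and 93 (81 higher, 12 lower) with quantile normalization. With the trend and the slide row as a block, which left 1 residual degree of freedom, it was 0. Without a position term the plain fit called 8 genes. Under normexp background correction the plain fit called 183 genes, 103 higher and 80 lower.

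Single genes higher in the duct included transcription factors and genes of epithelium. Tfap2b, an AP-2 factor of distal nephron and duct, was higher by at least 214-fold, adjusted p = 0.17, and its relative Tfap2a at least 77.5-fold, adjusted p = 0.17. The bHLH-PAS factor Sim1 was higher by at least 48.5-fold, adjusted p = 0.17. Kdf1, a regulator of epithelial differentiation, was higher by at least 33.6-fold, adjusted p = 0.17, and the adhesion molecule Nrcam at least 27.9-fold, adjusted p = 0.17. The apical sorting proteins Mal2 and Mal were higher by at least 67.2-fold, adjusted p = 0.17, and at least 58.1-fold, adjusted p = 0.21. Wnt9b, the duct signal that induces nephrons in neighbouring mesoderm, was higher by at least 53.4-fold, adjusted p = 0.21. H2-DMb1 and H2-DMb2, near-identical chaperones of antigen presentation, were higher by at least 13-fold (adjusted p = 0.17) and at least 80.5-fold, adjusted p = 0.23.

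Single genes lower in the duct had several roles. Adh1, an alcohol dehydrogenase that oxidises retinol, was lower in the duct by at least 110-fold, adjusted p = 0.25, and Aldh1a2, which makes retinoic acid in mesoderm, 23.9-fold (adjusted p = 0.22). Lrrn4, a mesothelial membrane protein, was lower by at least 13.8-fold, adjusted p = 0.22, and Bnc1, a zinc finger protein of mesothelium, at least 13.6-fold, adjusted p = 0.17. The secreted proteins Ptx3 and Tgfbi were lower by 15-fold and 22.4-fold, and the growth factor Csf3 at least 9.16-fold, adjusted p = 0.21. Foxd1, the transcription factor of kidney stroma, was lower by 20.4-fold, and the claudin gene Cldn11 19.1-fold. Hoxc10, a Hox gene of the lumbar region, was lower by 21.2-fold, and Fam181b 21.8-fold. The Wnt receptor Fzd1, the artemin co-receptor Gfra3, Sh3bgr and the phosphatase Ppef2 were lower by 7.94-fold, 7.56-fold, 11.3-fold and at least 4.2-fold (adjusted p = 0.17).

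Lists of epithelium and duct were higher in Hoxb7-GFP cells. Epithelial genes, which build junctions and apical polarity, were higher in the duct (20 of 20 higher, adjusted p = 2.1e-19, adjusted p = 0.34 with an estimated correlation), with a median log2 difference of 4.06 (3.74 on floored values). Adjusted over the list alone, 17 of them passed, against 0 over all genes. Cldn6 had the brightest signal of the list and was higher by 72.2-fold, Grhl2 at least 81.5-fold, adjusted p = 0.17, St14 at least 50.8-fold, adjusted p = 0.17, and Marveld3 at least 24.9-fold, adjusted p = 0.17. The other, dimmer probe of Marveld3 had a log2 difference of only 0.24, so that bound holds for 1 probe. The keratin gene Krt18 differed by 0.24, but by -0.66 without the caudal E9.5 duct array, -0.48 without the caudal Wt1-GFP array and 1.15 without the rostral E9.5 duct array. Duct transcription factors were higher (12 of 13 higher, adjusted p = 2.3e-13, adjusted p = 0.34 with an estimated correlation). Of these, 11 passed adjusted over the list alone against 0 over all genes, with Tfcp2l1 higher by at least 30.5-fold, adjusted p = 0.17. Bud tip genes, which answer GDNF through Ret, were higher (14 of 16 higher, adjusted p = 7e-10, adjusted p = 0.34 with an estimated correlation). Of these, 12 passed adjusted over the list alone against 0 over all genes. Here Cxcr4 was higher by 13.9-fold, and Gfra1 8.43-fold, while the ERK phosphatase Dusp6 differed by -0.23 (0.01 without the rostral E9.5 duct array, 0.1 with quantile normalization). Trunk and collecting duct genes were higher (15 of 18 higher, adjusted p = 1.7e-05, adjusted p = 0.34 with an estimated correlation). Of these, 7 passed adjusted over the list alone against 0 over all genes, among them Wfdc2 at 22.7-fold, Calb1 at 18.1-fold and Clu at 4.26-fold. Krt19, a keratin shared with coelomic epithelium, was instead lower by 9.71-fold.

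Mesenchymal and mesodermal lists moved the opposite way. Stromal genes were lower in the duct (18 of 18 lower, adjusted p = 4e-11, adjusted p = 0.34 with an estimated correlation). Of these, 14 passed adjusted over the list alone against 0 over all genes, among them Col3a1 18.6-fold, Snai2 15.2-fold, Col5a1 4.16-fold, Vim 2.46-fold, and Snai1 at least 7.09-fold, adjusted p = 0.25. Coelomic and gonadal ridge genes were lower (13 of 15 lower, adjusted p = 2.9e-05, adjusted p = 0.34 with an estimated correlation). Of these, 7 passed adjusted over the list alone against 0 over all genes. Emx2, a member shared with the duct, was higher by 11.6-fold, and Nr5a1 was flat at 0.08. Lateral plate genes were lower (12 of 14 lower, adjusted p = 0.00022, adjusted p = 0.34 with an estimated correlation). Of these, 6 passed adjusted over the list alone against 0 over all genes, with Pitx1 lower by at least 11.8-fold, adjusted p = 0.3, Fgf10 8.72-fold, Msx2 3.9-fold, and Bmp4 3.51-fold. Nephrogenic genes, which mark the precursors of nephrons, were lower (14 of 17 lower, adjusted p = 0.0058, adjusted p = 0.41 with an estimated correlation). The nephrogenic call ended without the caudal Wt1-GFP array (adjusted p = 0.15). Pax2 alone passed adjusted over the list alone, in the opposite direction, and the probe of Eya1 was flat at -0.08. Posterior Hox genes were lower (9 of 11 lower, adjusted p = 0.0091, adjusted p = 0.34 with an estimated correlation). Of these, 3 passed adjusted over the list alone against 0 over all genes, with Hoxa10 lower by 9.32-fold and Hoxd10 7.97-fold. On floored values the posterior Hox call ended (adjusted p = 0.1).

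Signalling lists differed between the reporters as well. Wnt response genes were higher in the duct (9 of 12 higher, adjusted p = 0.003, adjusted p = 0.41 with an estimated correlation), with the Wnt antagonist Dkk1 higher by 53.1-fold, Lgr5 at least 17.9-fold, adjusted p = 0.29, Tcf7 3.61-fold, and Rnf43 at least 6.19-fold, adjusted p = 0.17. The other, dimmer probe of Lgr5 had a log2 difference of only 0.02, so that bound holds for 1 probe. Notch genes were higher (8 of 14 higher, adjusted p = 0.04, adjusted p = 0.41 with an estimated correlation), led by Nrarp at 4.55-fold and Jag1 at 4.36-fold. The Notch call ended without the rostral (adjusted p = 0.14) or caudal E9.5 duct array (0.077) or either E10.5 array (0.062), and without the rostral Wt1-GFP array the direction turned (0.99). BMP response genes were lower (8 of 10 lower, adjusted p = 0.014, adjusted p = 0.34 with an estimated correlation), with Id2 lower by 2.17-fold but Id4 higher by 8.61-fold. The BMP call ended without the rostral E9.5 duct (adjusted p = 0.07) or Wt1-GFP array (0.11). Hedgehog response genes were lower (7 of 7 lower, adjusted p = 0.029, adjusted p = 0.41 with an estimated correlation), with Gli3 lower by 2.35-fold. The Hedgehog call ended without the caudal E9.5 duct (adjusted p = 0.24) or rostral Wt1-GFP array (0.19). Cell cycle genes were lower (16 of 17 lower, adjusted p = 0.00026, adjusted p = 0.41 with an estimated correlation), with log2 differences of -0.8 for Mcm6 and -0.64 for Mcm3. Glycolysis genes were lower (14 of 16 lower, adjusted p = 0.014, adjusted p = 0.41 with an estimated correlation), Aldoa at -0.74. The glycolysis call ended without the rostral E9.5 duct (adjusted p = 0.24) or Wt1-GFP array (0.26), and under quantile normalization (0.42). On floored values the BMP (adjusted p = 0.06) and Notch calls (0.05) ended. With the slide row as a block, the calls for Hedgehog (adjusted p = 0.95), Notch (0.89), cell cycle (0.33), glycolysis (0.33), Wnt (0.18), trunk (0.16) and BMP (0.091) genes all ended.

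Markers of other cell types differed between the sorts and bear on the lists above. Endothelial genes, despite the selection against Kdr, were higher in the duct cells (13 of 17 higher, adjusted p = 0.00026, adjusted p = 0.41 with an estimated correlation), with Cdh5 higher by at least 5.44-fold, adjusted p = 0.2, Icam2 at least 7.93-fold, adjusted p = 0.26, and Pecam1 3.9-fold. Etv2 was instead lower by 8.67-fold. Neural genes were higher (13 of 16 higher, adjusted p = 0.0091, adjusted p = 0.41 with an estimated correlation), with the neuronal tubulin Tubb3 higher by 9.84-fold. The neural call ended without the rostral E9.5 duct (adjusted p = 0.37) or Wt1-GFP array (0.06). Neural crest genes were higher (8 of 9 higher, adjusted p = 0.014, adjusted p = 0.34 with an estimated correlation), with Tfap2a and Erbb3 (at least 16.2-fold, adjusted p = 0.28), both also genes of epithelia, among them. The neural crest call ended without the rostral E9.5 duct (adjusted p = 0.11) or caudal Wt1-GFP array (0.084). Surface ectoderm genes were higher (9 of 11 higher, adjusted p = 0.003, adjusted p = 0.41 with an estimated correlation), with Tfap2c higher by at least 8.24-fold, adjusted p = 0.31 and Dlx5 at least 4.66-fold, adjusted p = 0.2. Posterior Hox genes moved with the limb mesoderm factors Pitx1 and Hand2 (at least 4.93-fold, adjusted p = 0.29), which were also lower in the duct. Retinoic acid response genes were not called (7 of 12 lower, adjusted p = 0.25, adjusted p = 0.41 with an estimated correlation). The median (-0.33) and mean (0.04) of that list had opposite signs. Among its members, Aldh1a2 and Dhrs3 (6.01-fold) were lower, while Cyp26a1, which degrades retinoic acid, was higher by at least 9.32-fold, adjusted p = 0.31.

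From E8.75 to E9.5 epithelial genes became brighter in the sorted cells, and endothelial and endoderm genes dimmer. Epithelial genes were higher at E9.5 (20 of 20 higher, adjusted p = 3.1e-14, adjusted p = 0.63 with an estimated correlation). Of these, 15 passed adjusted over the list alone against 0 over all genes. Duct trunk genes were higher too (13 of 18 higher, adjusted p = 0.041, adjusted p = 0.63 with an estimated correlation). Endothelial genes were lower at E9.5 (17 of 17 lower, adjusted p = 8.5e-11, adjusted p = 0.63 with an estimated correlation). Of these, 11 passed adjusted over the list alone against 0 over all genes. Endoderm genes were lower too (11 of 15 lower, adjusted p = 0.0071, adjusted p = 0.63 with an estimated correlation). Of these, 7 passed adjusted over the list alone against 0 over all genes. The E8.75 array is the only Hoxb7-GFP array whose labels do not state a selection against Flk1. In limma's plain fit 0 genes passed over all genes (lowest adjusted p = 0.19), 4603 had unadjusted p under 0.05 (2097 higher, 2506 lower), and 370 passed with the intensity trend (183 higher, 187 lower). The trend's count was 2 without the rostral E9.5 duct array, 0 without the caudal one or either E10.5 array, 174 without E11.5 and 602 without the rostral Wt1-GFP array. Floored values gave 167 calls in the plain fit (19 higher, 148 lower), normexp 99 (22 higher, 77 lower), and quantile normalization or the slide row block with the trend 0. The floored count is no support, since a gene at the floor on every split array has no spread there. The single E8.75 array adds none, so a gene bright on it alone can be called.

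Genes higher at E9.5 included epithelial and transcription factor genes. Tfap2b was higher by at least 393-fold, adjusted p = 0.19, and the claudin gene Cldn8 of the collecting duct at least 25.2-fold, adjusted p = 0.2. Marveld3 was higher by at least 45.8-fold, adjusted p = 0.19, Esrp1, which sets epithelial splicing, 67.4-fold, Epcam 20.7-fold, Krt8 6.64-fold, and Cdh1 at least 6.28-fold, adjusted p = 0.189. Ptpn3, a phosphatase at cell junctions, was higher by at least 46.6-fold, adjusted p = 0.19, the kinase gene Map3k21 at least 141-fold, adjusted p = 0.21, and the transcription factor gene Prdm16 at least 86.3-fold, adjusted p = 0.22. Unc13b was higher by at least 13-fold, adjusted p = 0.19, Sytl5 at least 10.2-fold, adjusted p = 0.19, and Ap3b2 at least 32.6-fold, adjusted p = 0.22. S1pr3, a receptor for sphingosine phosphate, was higher by 70.9-fold, and Gfra3 at least 8.52-fold, adjusted p = 0.19. The chemokine gene Cxcl14, the peptidase gene Cpa4 and the potassium channel gene Kcnj16 were higher by at least 57.8-fold, adjusted p = 0.2, at least 106-fold, adjusted p = 0.21, and at least 19.6-fold, adjusted p = 0.19. Among duct factors present from the start, Pax2 differed by -0.42 (0.11 without the rostral E9.5 duct array), Gata3 by -0.51 and Lhx1 by -1.11. Trunk genes such as Wnt9b (at least 69.7-fold, adjusted p = 0.23), Calb1 (33.5-fold) and Scnn1g (at least 6.96-fold, adjusted p = 0.21) were higher as well. The trunk call ended without the caudal E9.5 duct array (adjusted p = 0.28), under quantile normalization (0.091) and on floored values (0.053).

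Genes higher at E8.75 included markers of vessel and yolk sac. Lyve1, a hyaluronan receptor of lymphatic and yolk sac endothelium, was lower at E9.5 by at least 234-fold, adjusted p = 0.19. The sinusoidal endothelial genes Gpr182 and Stab2 were lower by at least 93.2-fold, adjusted p = 0.19, and at least 69.9-fold, adjusted p = 0.19. Cdh5 and Cldn5, junction genes of endothelium, were lower by 19.1-fold and 13.1-fold, and Kdr 4.68-fold. Mrc1 and Vsig4, receptors found on macrophages, were lower by at least 41.6-fold, adjusted p = 0.19, and at least 41.1-fold, adjusted p = 0.19, but the macrophage gene Tyrobp was not well above background at E8.75. The secreted yolk sac and liver proteins Afp and Ttr were lower by at least 33.8-fold, adjusted p = 0.19, and at least 16.6-fold, adjusted p = 0.19, Apoa1 at least 26.7-fold, adjusted p = 0.189, and the endoderm factor Hhex at least 30.3-fold, adjusted p = 0.189. Cd109, Fmo1 and Serpina3f were lower by at least 56.1-fold, at least 60-fold and at least 26.2-fold (adjusted p = 0.19, 0.19 and 0.19), and the olfactory receptor gene Olfr891 at least 4.84-fold, adjusted p = 0.19. The endoderm call ended without the rostral E9.5 duct array (adjusted p = 0.061). Glycolysis genes were lower at E9.5 (16 of 16 lower, adjusted p = 1.8e-05, adjusted p = 0.63 with an estimated correlation), with Pgk1 at -1.3 and Aldoa at -1.18. Cell cycle genes were lower too (16 of 17 lower, adjusted p = 0.00061, adjusted p = 0.63 with an estimated correlation), with Rrm2 at -1.23. Because endothelial and endoderm markers were so much higher at E8.75, these metabolic and cell cycle shifts cannot be placed in duct cells alone.

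From E9.5 to E10.5 trunk and epithelial genes became brighter in the sorted cells. Trunk genes were higher at E10.5 (16 of 18 higher, adjusted p = 9.4e-08, adjusted p = 0.43 with an estimated correlation). Of these, 8 passed adjusted over the list alone against 0 over all genes. Epithelial genes were higher at E10.5 (20 of 20 higher, adjusted p = 1.3e-10, adjusted p = 0.45 with an estimated correlation). Of these, 5 passed adjusted over the list alone against 0 over all genes. The epithelial sodium channel gene Scnn1b was higher by at least 12.8-fold, adjusted p = 0.52, Scnn1g 7.38-fold, the kidney cadherin gene Cdh16 10.8-fold, Krt7 6.28-fold, Krt8 3.94-fold, and Tjp3 4.2-fold. Tfcp2l1, which directs intercalated cell fate, was higher by 9.98-fold. By smallest p, Nhlrc4, the phospholipase gene Plch2, Bnipl and the laminin chain gene Lamb3 were higher by at least 7.11-fold, at least 9.83-fold, at least 8.81-fold and at least 4.14-fold (adjusted p = 0.52 for each), and the clotting factor gene F12 at least 1.84-fold, adjusted p = 0.52. In limma's plain fit 0 genes passed (lowest adjusted p = 0.52), 2203 had unadjusted p under 0.05, 1128 higher and 1075 lower, and 0 passed with the intensity trend.

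Mesodermal programmes were lower at E10.5. Stromal genes were lower (14 of 18 lower, adjusted p = 5.4e-09, adjusted p = 0.43 with an estimated correlation). Of these, 7 passed adjusted over the list alone against 0 over all genes, with Foxd1 lower by at least 8.58-fold, adjusted p = 0.52, Twist1 at least 15.8-fold, adjusted p = 0.54, and Vim 6.35-fold. Lateral plate genes were lower (12 of 14 lower, adjusted p = 0.00014, adjusted p = 0.43 with an estimated correlation), with Prrx1 lower by at least 6.89-fold, adjusted p = 0.52 and Msx2 at least 5.79-fold, adjusted p = 0.52. Nephrogenic genes were lower (15 of 17 lower, adjusted p = 0.00021, adjusted p = 0.47 with an estimated correlation), with Meox1 lower by at least 14.4-fold, adjusted p = 0.54. Somite genes were lower (11 of 14 lower, adjusted p = 0.014, adjusted p = 0.43 with an estimated correlation), a list that shares Meox1. Streak genes were lower at E10.5 (13 of 14 lower, adjusted p = 0.00028, adjusted p = 0.43 with an estimated correlation). The matrix glycoprotein gene Emilin2 was lower by at least 17.6-fold, adjusted p = 0.52, the hyaluronan synthase antisense gene Has2os 8.22-fold, and the cytokine signalling inhibitor Socs2 11.4-fold. FGF response genes were lower (11 of 12 lower, adjusted p = 5.9e-05, adjusted p = 0.43 with an estimated correlation), with Etv1 at -2.72. Cell cycle genes were lower (17 of 17 lower, adjusted p = 1.3e-05, adjusted p = 0.56 with an estimated correlation), Rrm2 at -0.95. Endothelial genes were lower (17 of 17 lower, adjusted p = 2.7e-06, adjusted p = 0.45 with an estimated correlation), with Emcn lower by at least 2.86-fold, adjusted p = 0.52. The shifts of these mesodermal lists therefore cannot be placed in duct cells alone. Anterior Hox genes were lower (12 of 15 lower, adjusted p = 0.0071, adjusted p = 0.61 with an estimated correlation), with Hoxc4 at -0.63. Posterior Hox genes were lower at E10.5 (9 of 11 lower, adjusted p = 0.0075, adjusted p = 0.43 with an estimated correlation), with Hoxd11 lower by at least 3.52-fold, adjusted p = 0.53. Both calls ended without the caudal E10.5 (adjusted p = 0.5 and 0.15) or rostral E9.5 duct array (0.13 and 0.062), and with the slide row as a block (0.5 and 0.15). On floored values the posterior Hox call ended (0.092). Neural genes were lower (13 of 16 lower, adjusted p = 0.019, adjusted p = 0.57 with an estimated correlation), with Sox2 lower by at least 4.96-fold, adjusted p = 0.52. That neural call ended without the rostral E10.5 array (adjusted p = 0.4) and its direction turned without the rostral E9.5 duct array (0.85).

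From E10.5 to E11.5 tip genes and genes that answer FGF and ERK signalling became brighter in the bud. Both lists hold Etv4, Etv5, Spry1 and Dusp6, so their calls are not separate. Tip genes were higher (16 of 16 higher, adjusted p = 8.5e-07, adjusted p = 0.98 with an estimated correlation). Of these, 5 passed adjusted over the list alone against 0 over all genes. The GDNF targets Etv4 and Etv5 were higher by 4.73-fold and 3.39-fold, the tip factors Sox9 and Sox8 2.96-fold and 6.5-fold, the tip ligand Wnt11 4.58-fold, Myb 2.8-fold, and Ret 2.56-fold (adjusted p = 0.45). These folds set the bud against the mean of both E10.5 parts, and tip genes were lower rostrally, so position is mixed into them. On the caudal E10.5 array alone Ret was at 1.79 against 2.15 in the bud, and Etv4 at 3.64 against 4.8. Against that array 15 of 16 tip genes were higher in the bud, with a median of 0.98, and against the rostral array 16 of 16, with a median of 2.26. FGF response genes were higher (12 of 12 higher, adjusted p = 1.5e-05, adjusted p = 0.98 with an estimated correlation), 12 of 12 of them also against the caudal array alone (median 1.09). Of these, 5 passed adjusted over the list alone against 0 over all genes, among them the feedback inhibitors Spry1 3.98-fold, Spred1 3.45-fold, and Spry4 at least 1.47-fold, adjusted p = 0.31. Retinoic acid response genes were not called as a list (6 of 12 higher, adjusted p = 0.91, adjusted p = 0.98 with an estimated correlation), although Dhrs3, Cyp26b1 and Rarb were higher by 5.4-fold, 6.38-fold and 3.27-fold. No list of other cell types was called, though the endothelial gene Icam2 was higher by a log2 difference of 2.68.

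Single genes at E11.5 rest on 1 array. Chdh, which oxidises choline, was higher by at least 34.5-fold, adjusted p = 0.24, the protocadherin gene Pcdhb4 at least 29.1-fold, adjusted p = 0.24, and Creb3l3, a transcription factor of liver, at least 5.15-fold, adjusted p = 0.24. The HMG box gene Ubtfl1 was higher by at least 6.58-fold, adjusted p = 0.24, and the receptor gene Vmn1r89 by at least 31.9-fold, adjusted p = 0.24. Pcp4, a calmodulin binding protein, was lower by at least 43.5-fold, adjusted p = 0.24, Ypel4 at least 37.4-fold, adjusted p = 0.24, and the kynurenine enzyme gene Kynu at least 10.6-fold, adjusted p = 0.24. Plch2 was lower by at least 9.56-fold, adjusted p = 0.24, and Gpatch3 10.9-fold. In limma's plain fit 0 genes passed (lowest adjusted p = 0.24), 3715 had unadjusted p under 0.05 (2123 higher, 1592 lower), 0 passed with the intensity trend, 19 with normexp and the trend, and 248 on floored values. The floored count is no support. A gene at the floor on every split array has no spread there, and the E11.5 array adds none, so this 1 bright array can give a call.

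Over the 4 stages as a line, epithelial and trunk genes had positive slopes with embryonic day, and endothelial and mesodermal genes negative ones. A slope does not mean a steady change. From E10.5 to E11.5 the median log2 difference was only 0.14 for epithelial and -0.08 for trunk genes. For stromal genes it was 0.23 from E8.75 to E9.5, -1.8 from E9.5 to E10.5 and 0.27 from E10.5 to E11.5. Epithelial genes led (20 of 20 higher, adjusted p = 4.4e-18, adjusted p = 0.44 with an estimated correlation). Of these, 19 passed adjusted over the list alone against 0 over all genes. Trunk genes had positive slopes (15 of 18 higher, adjusted p = 5.1e-07, adjusted p = 0.44 with an estimated correlation). Of these, 11 passed adjusted over the list alone. Among genes measured on all 6 duct arrays, Tfcp2l1 had a slope of 3.25 log2 per day, Calb1 2.97, Cdh16 2.42, St14 2.25, Esrp1 2.13, Epcam 1.9, Krt8 1.78, Grhl2 1.28 and Hoxb7 itself 0.61 (adjusted p = 0.14). Cldn8 stood below background at E8.75 and at -1.08, 0.46, 2.7, 2.44 and 4.05 on the later duct arrays, and Cldn3 at -2.3 at rostral E9.5 and 1.05 at E11.5. Tfap2b, Map3k21, Marveld3, Kcnj16 and the Nogo receptor relative Rtn4rl1 were below background at E8.75 as well and at 4.71, 3.87, 2.47, 1.35 and 1.46 at E11.5. The protease gene Adamts16, H2-DMb1 and Veph1, also below background at E8.75, were at 2.45, 1.56 and 0.97, and Pcdhb4 was above background at E11.5 alone (0.37). Tip genes had positive slopes (13 of 16 higher, adjusted p = 0.00057, adjusted p = 0.56 with an estimated correlation), Myb 1.16 and Ccnd1 0.65, but without E11.5 the direction turned (adjusted p = 0.96).

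Negative slopes lay in genes of mesoderm and vessel. Endothelial genes declined (17 of 17 lower, adjusted p = 6.5e-11, adjusted p = 0.44 with an estimated correlation). Of these, 12 passed adjusted over the list alone against 0 over all genes, with Kdr at -0.85 and Pecam1 at -1.08, and the call ended without E8.75 (adjusted p = 0.072). Endoderm genes declined (11 of 15 lower, adjusted p = 0.0026, adjusted p = 0.44 with an estimated correlation), and the call ended without E8.75 (adjusted p = 0.86). Cell cycle genes declined (17 of 17 lower, adjusted p = 4.6e-05, adjusted p = 0.63 with an estimated correlation), a call that ended without E8.75 (adjusted p = 0.71), though they were lower from E9.5 to E10.5 as well. Stromal genes declined (15 of 18 lower, adjusted p = 4.6e-05, adjusted p = 0.45 with an estimated correlation), with Vim at -1.59 and Zeb1 at -2.03. Lateral plate genes declined (13 of 14 lower, adjusted p = 4e-05, adjusted p = 0.44 with an estimated correlation), with Fgf10 at -2.09. Streak genes declined (12 of 14 lower, adjusted p = 3e-04, adjusted p = 0.44 with an estimated correlation). Of these, 7 passed adjusted over the list alone, and Cdx2 stood at 0.56 at E8.75 and -3.03 at caudal E9.5 and below background on the other duct arrays. Anterior Hox genes declined (12 of 15 lower, adjusted p = 0.0088, adjusted p = 0.66 with an estimated correlation), and the middle Hox gene Hoxc6 had a slope of -2.59. Nephrogenic genes declined (13 of 17 lower, adjusted p = 0.024, adjusted p = 0.63 with an estimated correlation), with Sall1 at -2.33. Early embryonic genes declined (10 of 14 lower, adjusted p = 0.022, adjusted p = 0.45 with an estimated correlation), with Lin28a at -1.86. Neural genes declined (14 of 16 lower, adjusted p = 0.036, adjusted p = 0.63 with an estimated correlation), and the duct gene Lhx1 had a slope of -0.82. Without E11.5 these 4 calls ended (adjusted p = 0.065, 0.071, 0.14 and 0.96), the neural one with its direction turned. The early embryonic call also ended without E8.75 (adjusted p = 0.096), and the neural one without the rostral E9.5 duct array (0.072). On floored values the anterior Hox (adjusted p = 0.054), nephrogenic (0.051), early embryonic (0.094) and neural calls (0.11) ended, and the neural one also with normexp (0.11). With the slide row as a block the anterior Hox (adjusted p = 0.68), nephrogenic (0.4), endoderm (0.18) and early embryonic calls (0.075) ended. Pcp4 was at 6.13 at E8.75, 0.11 at caudal E10.5 and below background at E11.5, and Meox1 at 3.23 at E8.75 and -4.22 at E11.5. The heparan sulphatase gene Sulf1 was at 3.71 at E8.75 and -3.59 at E11.5. Levels at E8.75 were 2.09 for Emilin2, 0.79 for the scavenger receptor gene Colec12, 2.68 for Gpr182, 3.24 for Lyve1, 1.35 for She, 2.43 for Has2os, 1.32 for the cytokine receptor gene Il2rg, 0.81 for Plpp4 and 0.94 for Rbm24, and all 9 were below background at E11.5. In limma's plain fit 0 genes passed (lowest adjusted p = 0.1), 4714 had unadjusted p under 0.05 (2524 with positive slopes), and 671 passed with the intensity trend (394 positive, 277 negative). That count was 1 without E8.75, 0 without either E10.5 array, 2122 without E11.5, and 1213 or 1181 without a Wt1-GFP array. Without E11.5 most of the genes counted with the trend had negative slopes, whereas positive slopes led with all arrays. Plain fits gave 909 with normexp, 577 on floored values and 204 without the position term. Genes at the floor on every split array have no spread, so a bright E8.75 or E11.5 array can by itself give a call among the 577. Quantile normalization with the trend gave 255, and the slide row block with the trend 0.

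Rostral and caudal parts differed in Hox code and tip genes, and at E9.5 in heart and coelomic genes. Posterior Hox genes were lower rostrally (10 of 11 lower, adjusted p = 2.1e-07, adjusted p = 0.39 with an estimated correlation). Of these, 3 passed adjusted over the list alone against 0 over all genes. Hoxd11 was lower rostrally by at least 24.6-fold (adjusted p = 0.73), Hoxc10 17.2-fold, Hoxd10 6.92-fold, and the caudal regulator Cdx1 at least 9.59-fold, adjusted p = 0.73. Tip genes were lower rostrally (13 of 16 lower, adjusted p = 1.2e-06, adjusted p = 0.39 with an estimated correlation). Of these, 3 passed adjusted over the list alone against 0 over all genes, with Ret lower by at least 2.47-fold, adjusted p = 0.73, Etv4 3.05-fold and Etv5 2.03-fold. FGF response genes were lower rostrally (12 of 12 lower, adjusted p = 1.2e-06, adjusted p = 0.39 with an estimated correlation), a list that shares Etv4, Etv5, Spry1 and Dusp6 with the tip list. Wnt response genes were lower (10 of 12 lower, adjusted p = 0.00056, adjusted p = 0.42 with an estimated correlation), a list that shares Cdx1. Streak genes were lower rostrally (12 of 14 lower, adjusted p = 0.00067, adjusted p = 0.39 with an estimated correlation), with Cdx2 lower by at least 1.86-fold, adjusted p = 0.73. Early embryonic genes were lower (11 of 14 lower, adjusted p = 0.011, adjusted p = 0.39 with an estimated correlation), with Lin28b at -1.05. The early embryonic call ended without either E10.5 array (adjusted p = 0.091). Cell cycle genes were lower rostrally (17 of 17 lower, adjusted p = 3.3e-07, adjusted p = 0.42 with an estimated correlation), Pcna at -0.61. Glycolysis genes were lower rostrally (14 of 16 lower, adjusted p = 0.00013, adjusted p = 0.42 with an estimated correlation), Slc2a3 at -1.91. Epithelial genes were lower rostrally (17 of 20 lower, adjusted p = 0.019, adjusted p = 0.63 with an estimated correlation), Grhl2 by at least 2.28-fold, adjusted p = 0.726. The median of the epithelial list was -0.97 in the E9.5 duct pair, 0.1 at E10.5 and 0.19 in Wt1-GFP cells, and the direction turned without either E9.5 duct array (adjusted p = 0.63). Germ cell genes were lower rostrally (6 of 9 lower, adjusted p = 0.012, adjusted p = 0.39 with an estimated correlation), among them Kit (-1) and Tfap2c (at least 3.57-fold, adjusted p = 0.726), both also genes of the bud, and Dazl, above background on the caudal E10.5 array alone. The germ cell call ended without either E10.5 array (adjusted p = 0.13). On floored values the streak (adjusted p = 0.18), germ cell (0.18), epithelial (0.055) and Wnt calls (0.05) ended, and the germ cell one also with normexp (0.066). With the slide row as a block the germ cell (adjusted p = 0.13) and early embryonic calls (0.091) ended. For position that block is the same fit as leaving out an E10.5 array, so it adds no separate check.

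On the rostral side were genes of heart, blood and neurons, used here as markers of other cells, beside mesodermal genes. Heart genes were higher rostrally (10 of 11 higher, adjusted p = 3.9e-05, adjusted p = 0.43 with an estimated correlation). Of these, 4 passed adjusted over the list alone against 0 over all genes, with the atrial light chain gene Myl7 higher by at least 6.96-fold, adjusted p = 0.73, Tnni1 2.7-fold, and Gata4 at least 18.7-fold, adjusted p = 0.73. The median rostral minus caudal difference of the list was 2.77 in the E9.5 duct pair and 1.93 in Wt1-GFP cells but 0.08 in the E10.5 pair. Coelomic genes were higher (15 of 15 higher, adjusted p = 3e-05, adjusted p = 0.39 with an estimated correlation), where Gata4 is shared and Gata6 was higher by at least 3.01-fold, adjusted p = 0.726. Stromal genes were higher rostrally (14 of 18 higher, adjusted p = 0.0018, adjusted p = 0.42 with an estimated correlation), Pdgfra by at least 2.22-fold, adjusted p = 0.726. Neural genes were higher (16 of 16 higher, adjusted p = 0.0081, adjusted p = 0.44 with an estimated correlation). In the E10.5 pair the medians of coelomic (0.13), stromal (-0.01) and neural genes (-0.18) were near 0 or lower rostrally, against 1.62, 1.2 and 1.1 in the E9.5 duct pair. The rostral neural call ended without either E9.5 duct array (adjusted p = 0.34). Blood genes were higher (13 of 14 higher, adjusted p = 0.02, adjusted p = 0.39 with an estimated correlation), the band 3 gene Slc4a1 at 1.17, with medians of 0.04 and 1.44 in the E9.5 and E10.5 duct pairs. The blood call ended without either E10.5 array (adjusted p = 0.41), on floored values (0.15), with normexp (0.079) and with the slide row as a block (0.41). Middle Hox genes were higher (10 of 12 higher, adjusted p = 0.015, adjusted p = 0.48 with an estimated correlation), Hoxc6 at 2.15 and Hoxb9 at 1.47, though not in the Wt1-GFP pair (median -0.16). The middle Hox call ended without either E10.5 (adjusted p = 0.19) or E9.5 duct array (0.097), and with the slide row as a block (0.19). BMP response genes were higher (10 of 10 higher, adjusted p = 0.0014, adjusted p = 0.39 with an estimated correlation), Msx2 at least 2.23-fold, adjusted p = 0.73. The rostral BMP call ended without either Wt1-GFP array (adjusted p = 0.086). By smallest p, Ptx3, Kynu, the nephron inducer Wnt4 and the phospholipase gene Plcb1 were higher rostrally by 7.23-fold, 5.65-fold, 4.42-fold and 5.34-fold, and Igsf1 at least 3.99-fold, adjusted p = 0.73. The secreted protein gene Egfl6 was lower rostrally by at least 3.68-fold, adjusted p = 0.73, the tryptophan enzyme gene Ido2 at least 4.18-fold, adjusted p = 0.73, and Socs2 4.05-fold. In limma's plain fit 0 genes passed (lowest adjusted p = 0.73), 2005 had unadjusted p under 0.05 (1183 higher, 822 lower), and 0 passed with the intensity trend.

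**Figure D2:**
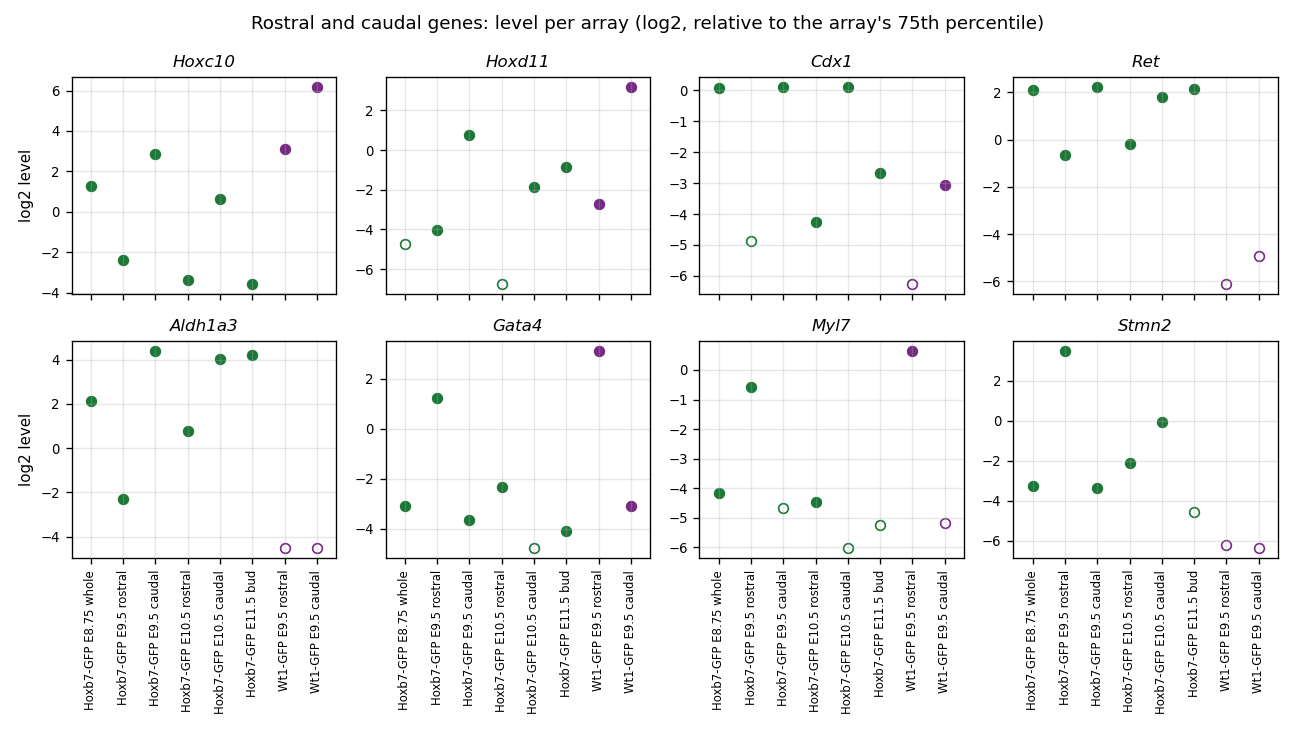
Level of 8 rostral or caudal genes on each of the 8 arrays, as log2 signal relative to the 75th percentile of the array. Each point is 1 array, green for Hoxb7-GFP and purple for Wt1-GFP, filled where the gene was well above background and open where it was not.

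Whether position acted differently in duct and intermediate mesoderm was asked of each gene by an interaction term. Aldh1a1, an enzyme that makes retinoic acid, was the 1 gene past the threshold with the intensity trend (adjusted p = 0.032 with the trend). In the duct it was higher caudally, at 4.03 against -0.07 at E9.5 and 3.94 against 0.1 at E10.5. In Wt1-GFP cells it was at -1.14 rostrally and caudally under that array's dimmest well-above level of -4.22. With that level in its place the log2 difference is -7.06, a bound. In limma's plain fit 0 genes passed (lowest adjusted p = 0.81), 1732 had unadjusted p under 0.05, and the call for Aldh1a1 ended without the E11.5 array, and with quantile normalization, normexp or the deposited matrix (0 genes with the trend in each).

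Across all arrays the lists parted the samples along the same axes. Epithelial genes had a median level of -1.75 at E8.75, 2.9 at E11.5 and -2.6 in caudal Wt1-GFP cells. Endothelial genes stood at 1.32 at E8.75, and heart genes at -0.06 and -0.65 on the rostral E9.5 arrays. For every called list in the 6 comparisons the median, the mean and the test had the same direction. For some lists without a call, such as middle Hox genes between reporters and tip genes from E8.75 to E9.5, they differed in sign. The immediate early and heat shock list, a gauge of handling during dissociation, was called in no comparison. Its adjusted p was 0.7 between reporters, 0.23 from E10.5 to E11.5 and 0.13 along embryonic day (0.9, 0.98 and 0.69 with an estimated correlation). Its median level was nonetheless 0.57 at E8.75, 1.7 and 1.67 at rostral and caudal E9.5, 2.89 and 1.9 at E10.5, and 3.26 at E11.5. In Wt1-GFP cells it was 0.56 rostrally and 1.25 caudally. A difference in handling between the stages therefore stays open.

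**Figure D3:**
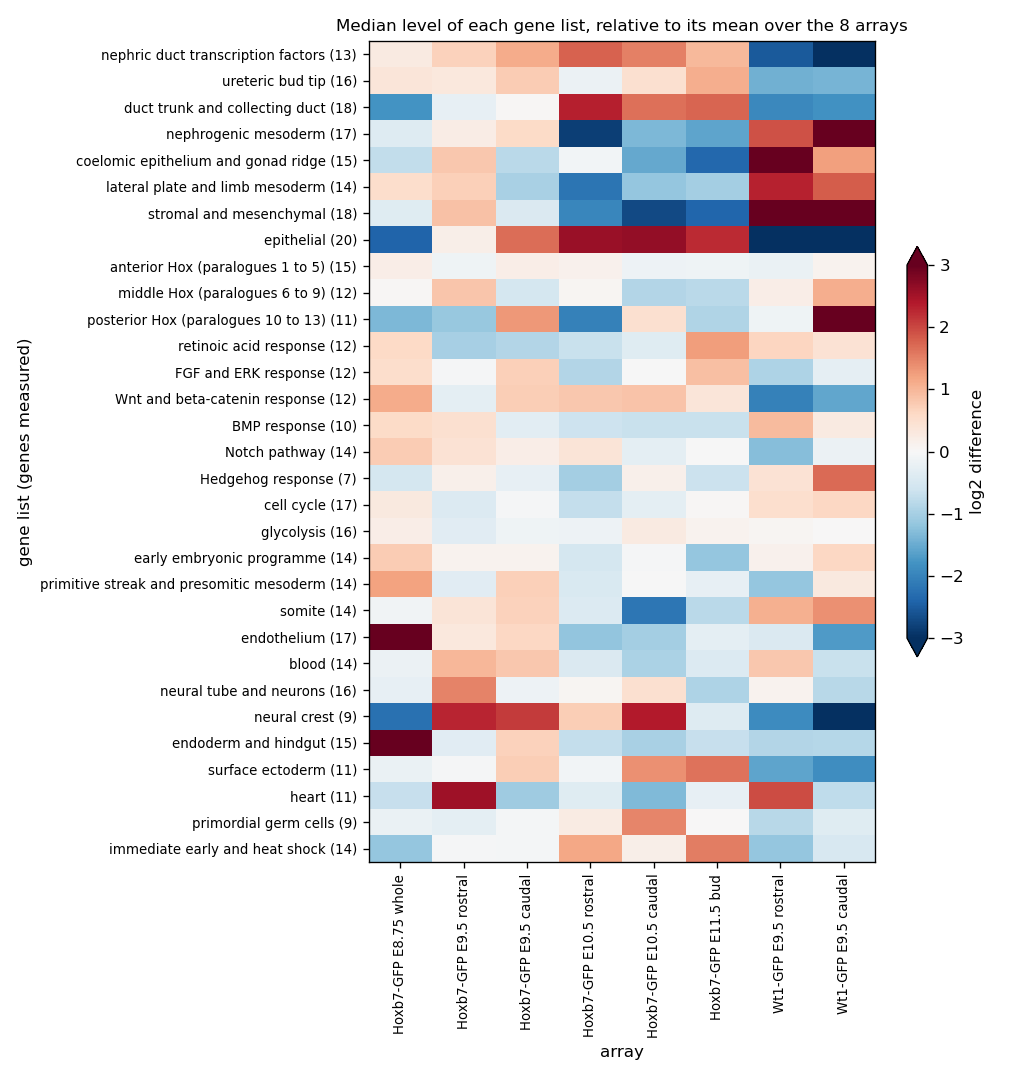
Median log2 level of each of the 31 gene lists on each of the 8 arrays, minus the mean of that list over the arrays. Columns are arrays, each line of the map is a list with its number of measured genes in brackets, and colour gives the log2 difference.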

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

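All tests in this part were chosen after the results were seen. No group had as many as 4 arrays, so no test for outlying samples was run. Camera on the interaction of position with reporter set the rostral minus caudal difference of a list in the duct against that in Wt1-GFP cells, and 6 lists passed, each with adjusted p = 0.88 with an estimated correlation. The Wt1-GFP side is 1 rostral against 1 caudal array, so the spread of each gene came from the duct pairs alone, with 1 residual degree of freedom. List p-values at the preset correlation rest on the spread over genes and do not carry that limit. Tip genes were lower rostrally in the duct more than in Wt1-GFP cells (median interaction -0.68, adjusted p = 0.016), with rostral minus caudal medians of -1.25 and -1.19 in the duct pairs of E9.5 and E10.5 and -0.26 in Wt1-GFP cells, where some tip genes such as Ret were below background on both arrays, which shrinks that difference. Nephrogenic genes differed by 1.03 (adjusted p = 0.0011), with medians of 0.15 and 0.34 in the duct pairs and -0.79 in Wt1-GFP cells. Anterior Hox genes differed by 0.59 (adjusted p = 0.0045; 0.19 and 0.28 against -0.41), and middle Hox genes by 0.61 (adjusted p = 0.008; 1.2 and 0.83 against -0.16). Notch genes differed by 0.83 (adjusted p = 0.0022), with 0.42 and 0.65 in the duct against -0.13. Endothelial genes differed by -0.45 (adjusted p = 0.016), with -0.8 and -0.08 in the duct against 0.54.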

How the results depend on the processing

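Settings with slide rows, floored values, the intensity trend combined with another change, and list tests without an array were chosen after the data were seen. The interaction was not fitted with the slide row block, and its leave-outs were of the E8.75 and E11.5 arrays alone. Gene counts past adjusted p 0.05 were 0 in the plain fit for every comparison, and stayed 0 under quantile normalization, the deposited matrix, other filters, the mean over probes, other sets of arrays, the slide row block (with the trend as well) and plain leave-outs. For Hoxb7-GFP against Wt1-GFP they were 183 with normexp, 632 with the intensity trend, 8 without the position term, 93 with quantile normalization and the trend, 403 with normexp and the trend, 700 with the matrix and the trend, and, with the trend and 1 array left out, 0 to 613 (600, 613, 433, 362, 174, 1 and 0). From E8.75 to E9.5 they were 99, 370, 16, 0, 543, 470 and 0 to 602 (602, 537, 174, 2 and 0) in the same order, and 167 on floored values. From E10.5 to E11.5, floored values gave 248 and normexp with the trend 19. Along embryonic day they were 909, 671, 204, 255, 1043, 715 and 0 to 2122 (2122, 1213, 1181, 797, 626, 1 and 0), and 577 on floored values. Position gave 0 to 1 with the trend and 1 array left out, and the interaction 1 with the trend (0 to 1). Counts on floored values in comparisons with the E8.75 or E11.5 array are no support. There a gene at the floor on every split array has no spread, and 1 bright array can give a call. Of the 632 genes between reporters, 93 also passed with quantile normalization and the trend and 173 with normexp. Lists past the threshold numbered 19, 6, 13, 2, 13 and 17 in the 6 comparisons, 0 with an estimated correlation, and 0 with fry except 2 along embryonic day. Lists with an estimated correlation below 0 were lost too. Between reporters these included lateral plate (-0.05) and posterior Hox genes (-0.06), each with adjusted p = 0.34. With an estimated correlation camera tests on the 2 residual degrees of freedom, while at the preset it takes them from the number of genes. A call lost with the estimated correlation can therefore follow from the few arrays. It does not by itself show that the genes of a list vary together. From E10.5 to E11.5 normexp gave 4, the slide row block 6 and leave-outs 2 to 6. Without 1 array, the direction turned for Notch genes between reporters (adjusted p 0.00026 to 0.99), neural genes from E9.5 to E10.5 (6.8e-05 to 0.85), tip genes (0.00014 to 0.96) and neural genes (0.00038 to 0.96) along embryonic day, and epithelial genes by position (3.9e-05 to 0.63). Of 70 list calls, 68 were kept under quantile normalization, 67 under normexp, 70 with the matrix, 70 without a filter, 53 with the slide row block and 56 on floored values. Among named genes the direction turned between reporters for Dusp6 (0.1 with quantile normalization, -0.48 to 0.01 without 1 array) and Krt18 (-0.66 to 1.15 without 1 array), and for Pax2 from E8.75 to E9.5 (-0.94 to 0.11 without 1 array). The labels give no replicate numbers shared between groups, so groups were not paired with each other. Rostral and caudal parts of a group were compared as pairs through the group and position terms.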

Other observations

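All tests in this part other than the splits of the samples were chosen after the results were seen. An enzyme gene of retinoic acid synthesis and a Wnt ligand gene were brighter caudally in the duct. The enzyme gene Aldh1a3 was at 4.39 caudally and -2.31 rostrally in the E9.5 duct, at 4.04 and 0.76 at E10.5, and at 4.22 in the bud. The ligand gene Wnt6 was at 0.48 and -2.6 at E9.5, 0.59 and -3.41 at E10.5 and 0.49 in the bud. Neither passed as a single gene. Aldh1a2, another enzyme of that synthesis, ran the other way at E9.5, at -0.37 rostrally and -1.22 caudally, and the retinoic acid list was not called by position (adjusted p = 0.87, 0.88 with an estimated correlation).

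Among immediate early genes, which dissociation can induce within minutes, Fos and Zfp36 were brightest on the rostral E10.5 and E11.5 arrays. Fos was at 3.03 and 3.37 there and between -0.21 and 1.41 elsewhere, and Zfp36 at 4.73 and 3.56. Atf3 was instead brightest at E8.75 (0.51). The list was called in no comparison, although its median level was 0.57 at E8.75 and 3.26 at E11.5. The embryonic globin gene Hbb-y was dimmest on the caudal E10.5 array, at -3.64 against 4.27 on the caudal E9.5 duct array.

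Endothelial and endoderm transcripts were far brighter on the E8.75 array, where 17 of 17 endothelial genes were higher than on each other Hoxb7-GFP array. This count restates the pattern and argues against no source. Cells of another type, in a sort whose labels state no selection against Flk1, and earlier duct cells that transcribe such genes themselves cannot be told apart, because stage and sort are confounded on 1 array.

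Neuronal and heart transcripts stood out on the rostral E9.5 duct array, with Stmn2 at 3.47 and Myl4 at 3.72. Of the heart genes, 9 of 11 were higher rostrally in both E9.5 pairs, duct and Wt1-GFP. This count restates the pattern, and a rostral difference of the sorted cells themselves would give it too. It therefore does not tell such a difference from cells of another type. For neural genes the source stays open as well, with 10 of 16 highest on the rostral E9.5 duct array. Median rostral excess of the heart list was 2.77 in the duct pair and 1.93 in the Wt1-GFP pair, so at E9.5 it does not rest on 1 array, but 0.08 in the E10.5 pair. That of the neural list was 1.1 and 0.36, and scatter of the rostral E9.5 duct array stays open for it. The sort for GFP stated for every sample should exclude heart cells and neurons unless they carry the reporter or slip through, which was not tested, and no Flk1 gate would remove them. A biological difference of the rostral duct was not tested apart from such cells.

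The reporter difference at E9.5 might have followed the slide row, because both Wt1-GFP arrays lay in the second. Over the 1364 genes with at least a 4-fold difference, duct arrays of that row kept a median share of 0.92 of it (quartiles 0.57 to 1.26), and the caudal E10.5 array alone 0.95 (lower quartile 0.64), which argues against the row as its whole source. A smaller part played by the row stays open. With the row as a block and the trend, 0 of the 632 genes passed (lowest adjusted p = 0.56), and 7 of 19 list calls ended. The block rests on the E10.5 pair alone, so these losses cannot be laid to the row rather than to a position difference particular to E10.5. For these 632 genes the median absolute log2 difference was 2.15 without the block and 1.9 with it, and the median SE 0.26 and 0.49. The gene calls ended mainly because the SE grew and residual degrees of freedom fell from 2 to 1. For position, the 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05 (smallest 0.1). Some of them put both arrays of a rostral and caudal pair on the same side. At least as many genes at unadjusted p under 0.05 came from 3 splits, the real one among them. The real split gave 2005 and the highest other 2028, which gave 0 genes past adjusted p 0.05.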
